A study of Mus musculus with 8 samples.

How the data were processed

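The samples were 8 RNA-seq libraries from ASZ cells, a mouse basal cell carcinoma line, in 4 groups of 2 libraries. Wild-type ASZ cells and ASZ cells expressing RasV12, an activated form of the small GTPase Ras, each received DMSO (the vehicle) or CBD. The labels do not spell out CBD and give neither its dose nor the time of exposure, and they do not say which Ras gene the construct carries. RNA came from adherent cells by a column kit and libraries were made from total RNA with the Illumina TruSeq RNA kit, per the labels' protocols. The labels give replicate numbers but do not say whether replicates were separate cultures, so the p-values rest on libraries that may be technical replicates. How the authors' test estimated the spread of each gene is not given in the sources used here.

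Reads were handled with TopHat and Cufflinks on the mm9 build, per the submitters' processing notes, with no versions given in the sources used here. The authors' deposited tables, 1 per line, held for each gene symbol 1 FPKM value for DMSO and 1 for CBD, each over the 2 libraries of the group per the file headers. They also held the authors' p-value for CBD against DMSO, with no adjusted value. The deposited tables held no value per library, so no SD between libraries, no test with another model and no fit without a library could be made. The authors' filtered sheets held log2 fold changes of the genes the authors kept. They were used only as counts. The log2 fold change column of the whole tables was not used, and changes were taken from the FPKM of both tables in the same way. In the RasV12 table that column held infinite and unreadable cells.

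The p-values of the 2 tables differed in kind. All tested genes of the RasV12 table had p-values in steps of 5e-05, with 5e-05 the lowest, which 1707 of the genes used shared. In the ASZ table, 8.66% of p-values lay on such steps and 554 genes were listed at a p-value of 0. The tables were therefore used as 2 separate analyses, with p-values adjusted within each. The test of the difference between the lines still set standard errors from both kinds of p-value against each other, which is a limit of that test. The tables also listed some genes under different symbols, such as Hras1 in the ASZ table and Hras in the RasV12 table. Whether the same program version and gene annotation made both tables is not given in the sources used here.

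Rows without a gene name (199 in the ASZ table) and rows whose name had become a date (26 in each table) were left out. Older symbols were replaced through NCBI RefSeq synonyms where 1 gene carried them (1644 rows in the ASZ table and 1277 in the RasV12 table). Where a symbol stood on several rows (1179 and 412 rows), the highest row was used if every other row was under 10% of it, and otherwise none. This rule was chosen after the data were seen, because leaving out all repeated symbols had dropped well-expressed genes. It left out 53 and 5 rows at 1 FPKM or more. A p-value of 1 marked a gene without a test. Genes with a test and at least 1 FPKM in at least 1 group were used, 10703 in the ASZ table and 11075 in the RasV12 table, and 12 and 20 genes at that level had no test. Reads of near-identical genes, such as the histones, the paired copies of the inducible Hsp70 genes, keratins and ribosomal protein genes with pseudogenes, could have been split between copies.

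The deposited p-values were adjusted with the Benjamini-Hochberg method over the genes used, because the tables held no adjusted value, and genes under 0.05 were called higher or lower. Changes are given on the log2(FPKM + 1) scale, which understates the change of low genes. A standard error of the log2 FPKM ratio was implied from each p-value, as the size of the ratio divided by the normal quantile of p. It is an upper bound where p was at its lowest value. Its median was taken over genes with a p-value above 0.01 only. There it was 0.47 at 1 to 3 FPKM and 0.22 at 100 FPKM or more in the ASZ table. In the RasV12 table it was 0.51 and 0.27, so precision rose with level among these genes. The difference of the lines' log2 ratios was tested with a two-sided normal test on these standard errors, with Benjamini-Hochberg adjustment over 10405 genes. DMSO levels of the 2 lines came from different tables. They were compared without a test, as log2(FPKM + 1) minus its median over 10925 genes.

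Depth was estimated from the step between the lowest FPKM values of genes with up to 3 exons. The step was taken as 1 fragment in 1 of 2 equally deep libraries, with FPKM per 1e6 of the group's own fragments. The depth was then 13.98 M fragments (M is 1e6) per library for ASZ DMSO, 13.79 M for ASZ CBD, 16.08 M for RasV12 DMSO and 10.59 M for RasV12 CBD. A scale factor on a group's FPKM would change the step just as depth does. The higher step in RasV12 CBD (0.0472 FPKM times kb, against 0.0311 in RasV12 DMSO) can therefore reflect scaling, lower depth or both. Whole reads could not be recovered, because each value mixes 2 libraries.

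The FPKM of a table were not on 1 common total. The sum of FPKM rose from 371297 to 531898 with CBD in ASZ cells and from 437048 to 658792 in RasV12 cells. The sum of FPKM times transcript length in kb, which is in proportion to sequenced fragments, rose from 888427 to 961905 and from 980515 to 1299679. Setting these last sums equal (equal fragment mass) would lower all log2 changes by 0.11 in ASZ cells and 0.41 in RasV12 cells, and setting the FPKM sums equal would lower them by 0.52 and 0.59. The median log2 ratio as deposited was -0.44 in ASZ cells and -0.01 in RasV12 cells. Each direction was checked under both of these scalings, which were chosen after seeing the data, with p-values recomputed from the implied standard errors. Since these are upper bounds at the lowest p-values, calls lost under a scaling, above all in the RasV12 table, can reflect that bound and not a small change. Genes that did not pass as deposited could pass as lower under a scaling, which is not given for each.

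The 35 gene lists, the rule for the genes named and the tests, with a form for tables without values per library, were fixed before the data were examined. The handling of repeated symbols, the scalings by fragment mass and FPKM sum, the length corrections and all tests of explanations in the closing section were chosen after. Per list the text gives the members tested, the members called higher and lower over all genes and adjusted over the list alone, and the list's median with its percentile among the medians of 10000 random lists of the same size matched on mean expression (20 bins), or with the median of those lists, as a description. Marker lists of other cell types, with 1 or 2 members tested, are given without these. Genes named were the 10 highest and the 10 lowest changes past the threshold per line, the 5 highest and the 5 lowest differences between lines, up to 2 rising and 2 falling members per list and 31 genes fixed in advance. Predicted genes and microRNA, small nucleolar RNA and mitochondrial genes were skipped among the ranked names, and a few genes that the rule names are not reported here. Transcript length, the longest protein-coding transcript in GENCODE M21, was known for 94.3% of the ASZ genes and 93.8% of the RasV12 genes. It comes from a later build than mm9, so it was used only as a gene property and no coordinates are given.

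The steps were tested on simulated tables with 200 changed genes per line. In the ASZ table (6334 genes) 52% of 2-fold and 91% of 4-fold changes were recovered. In the RasV12 table (8326 genes) the shares were 40% and 84%. For the difference between the lines (5523 genes) they were 21.3% and 69.2%. Calls on unchanged genes numbered 8, 4 and 3. The simulated noise was drawn from the implied standard errors that the test itself uses, on genes with a deposited p-value above 0.001, so these shares test the calculation and not the errors. Of 200 random lists, 5.5% fell outside the central 95% of their matched lists.

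The alternatives were other FPKM filters, thresholds, adjustments, pseudocounts, scalings, a correction for transcript length and the authors' filtered sheets. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.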

Results

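RNA was measured in ASZ cells, a mouse basal cell carcinoma line, in 4 groups of 2 libraries: wild-type ASZ cells and ASZ cells expressing RasV12 (called RasV12 cells here), each with DMSO or CBD. Each group had 1 FPKM value per gene, so no value per library and no SD can be given. The error given with a log2 ratio is the standard error implied by the authors' p-value. The p-values rest only on these libraries, and how the authors' test estimated the spread of each gene is not given. The depth was estimated as 13.98 M and 13.79 M fragments (M is 1e6) per library for ASZ DMSO and CBD, and 16.08 M and 10.59 M for RasV12 DMSO and CBD. These estimates take each group's FPKM as per 1e6 of its own fragments, so unequal scaling of the groups would shift them. The lower value for RasV12 CBD can therefore reflect scaling and not depth. The 10 most abundant genes held 8.43% and 11.2% of the FPKM in ASZ DMSO and CBD, and 9.05% and 8.77% in RasV12 DMSO and CBD. The median log2 FPKM ratio of CBD to DMSO was -0.44 in ASZ cells and -0.01 in RasV12 cells, and the tables were not scaled to a common total. Each list median is therefore set beside the median of random lists of like expression, and directions that turned under another scaling are given.

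The comparison of CBD with DMSO in ASZ cells asks how this agent changed expression in the wild-type line, in a series whose title concerns primary cilia and the Hedgehog and Ras/MAPK pathways. Gli1, the transcription factor that is itself a Hedgehog target, fell with CBD from 2.73 to 0.682 FPKM (log2 ratio -1.998, SE 0.39, adjusted p 1.8e-06). Ptch1, the Hedgehog receptor and a target, fell from 1.10 to 0.409 FPKM (adjusted p 0.0036), and both are low values. Their transcripts are 4057 and 7725 nt long, and of all genes in their bins of transcript length 54.4% and 78.8% were called lower. Most immediate early genes were higher, with Egr1 at 2.80 FPKM in DMSO and 83.0 in CBD and Fos at 0.278 and 23.9. Most genes of the cell cycle lists were lower, and Mki67, a marker of proliferating cells, was at 19.0 and 4.44 FPKM. The Mki67 transcript is 10061 nt long and lies in the same length bin as that of Ptch1, where 78.8% of genes were called lower.

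Of 9 Hedgehog target genes tested, 6 fell and 0 rose, and 6 fell and 0 rose adjusted over the list alone. Their median log2 change was -0.58, at the 37.8 percentile of random lists with a median of -0.46, a gap within the spread of such lists. With transcript length matched too, it was at the 59.2 percentile. Foxf2, a forkhead transcription factor, fell from 2.12 to 0.333 FPKM, and Hhip, a Hedgehog-binding protein, was listed at 0 in both groups. Of 19 Hedgehog pathway components, 12 fell and 2 rose (12 and 2 adjusted over the list alone). The median was -0.93, at the 2.88 percentile, and at the 14.3 percentile of lists matched on transcript length too. Smo, the signal transducer of the pathway, fell from 55.7 to 28.8 FPKM (log2 ratio -0.95, SE 0.22). Gas1, a co-receptor, fell from 65.9 to 4.21 FPKM, Gli2, a transcription factor, from 2.01 to 0.208, and Sufu, an inhibitor of the Gli factors, from 11.1 to 1.503. Grk2 and Prkaca, kinases that act on the pathway, rose from 24.03 to 39.7 and from 61.0 to 101 FPKM, but neither passed with equal FPKM sums.

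Of 65 genes of cilium assembly and intraflagellar transport, 7 rose and 20 fell (7 and 20 adjusted over the list alone). The median was -0.25, above that of random lists (-0.59, 99.2 percentile). With equal FPKM sums 0 rose and 37 fell. Arl3, a small GTPase of ciliary transport, rose from 54.7 to 96.3 FPKM and Ift22 from 23.8 to 46.7, both without passing under equal FPKM sums. Ift80, part of the transport particle, fell from 6.68 to 1.44 FPKM, Ttc30b from 2.05 to 0.0835 and Arl13b, a ciliary GTPase, from 2.70 to 1.496. Kif3a, a subunit of the ciliary motor kinesin-2, was at 8.02 and 7.16 FPKM (adjusted p 0.60), and Ift88 at 1.23 and 1.92 (adjusted p 0.13). With equal FPKM sums Kif3a passed as lower.

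Of 21 Ras/MAPK output genes, 6 rose and 7 fell (7 and 7 adjusted over the list alone). The median was -0.06 against -0.59 in random lists (98.1 percentile), and with equal FPKM sums 5 rose and 10 fell. Dusp4 and Dusp6, phosphatases that act on MAP kinases, rose from 0.312 to 3.90 and from 4.48 to 9.57 FPKM, the latter without passing under equal FPKM sums. Etv4, an ETS transcription factor, rose from 3.61 to 11.1 FPKM and Spry1, a feedback inhibitor, from 1.22 to 6.70. Spred2, another inhibitor, fell from 23.4 to 2.29 FPKM and Has2, a hyaluronan synthase, from 4.64 to 0.112. Of 25 Ras/MAPK pathway components, 2 rose and 15 fell (2 and 15 adjusted over the list alone), at a median of -0.82 (0.71 percentile, and 10.1 with transcript length matched). The receptors Fgfr2 and Met fell from 51.9 to 5.74 and from 46.2 to 7.37 FPKM. Hras was at 59.9 and 74.98 FPKM (adjusted p 0.27) and Nras at 30.3 and 28.1 (adjusted p 0.70).

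Of 18 immediate early genes, 13 rose and 2 fell (13 and 2 adjusted over the list alone), with a median of 1.21 against -0.14 in random lists (100 percentile), and with equal FPKM sums 11 rose and 2 fell. The 2 that fell were Myc, from 36.5 to 13.7 FPKM, and Klf4, from 63.6 to 31.3. Of 17 target genes of YAP/TEAD and SRF, which regulate growth and the cytoskeleton, 3 rose and 9 fell (3 and 10 adjusted over the list alone), at a median of -0.84 (0.09 percentile). Ajuba fell from 55.7 to 5.35 FPKM and Amotl2 from 22.8 to 3.24, while Tpm1 rose from 206 to 416, without passing under equal FPKM sums.

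Of 30 G1/S and DNA replication genes, 24 fell and 0 rose (25 and 0 adjusted over the list alone), at a median of -0.90 (0.05 percentile). Of 35 G2/M and mitosis genes, 26 fell and 0 rose (26 and 0 adjusted over the list alone), at a median of -1.22 against -0.19 in random lists. Fen1, a nuclease of DNA replication, fell from 38.8 to 3.81 FPKM, and Ccnb1, the mitotic cyclin, from 43.9 to 7.04. Cdkn1a, an inhibitor of the cell cycle, was at 27.3 and 28.9 FPKM (adjusted p 0.80).

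Of 27 genes of the integrated stress and unfolded protein responses, 12 rose and 5 fell (12 and 5 adjusted over the list alone), at a median of 0.46 (99.5 percentile), but with equal FPKM sums 5 rose and 8 fell, at a median of -0.06. Ddit3, a transcription factor of these responses, rose from 17.0 to 75.8 FPKM. Of 14 heat shock genes, 9 rose and 4 fell (9 and 4 adjusted over the list alone), at a median of 0.73 (89.3 percentile, and 98.9 with transcript length matched), and with equal FPKM sums 3 rose and 4 fell. Hspa1a, an inducible Hsp70, rose from 2.31 to 26.6 FPKM and Hspb1 from 976 to 3149.8, and Bag3, a co-chaperone, fell from 36.0 to 16.6. All 32 ribosomal protein genes listed rose, at a median of 1.20 against 0.81 (32 adjusted over the list alone), 28 of them with equal FPKM sums, at a median of 0.68. Of 30 nuclear oxidative phosphorylation genes, 23 rose and 0 fell (23 and 0 adjusted over the list alone), at a median of 0.76 (93.9 percentile, and 66.2 with transcript length matched), and with equal FPKM sums 5 rose and 1 fell.

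Of 23 basal keratinocyte genes, 5 rose and 7 fell (5 and 7 adjusted over the list alone), at a median of 0.02 against 0.53 (0.02 percentile, and 16.5 with transcript length matched), and with equal FPKM sums 0 rose and 12 fell, at a median of -0.50. Trp63, the basal lineage transcription factor, fell from 64.6 to 20.7 FPKM and Krt15 from 146 to 33.7. Krt17 rose from 2744 to 5701 FPKM, without passing under equal FPKM sums. Krt5 was at 4360.05 and 6226 FPKM (adjusted p 0.11) and Krt14 at 5277 and 4109 (adjusted p 0.24). Of 12 keratinocyte differentiation genes, 2 rose and 7 fell (2 and 7 adjusted over the list alone), at a median of -0.54 (47.8 percentile), and with equal FPKM sums 0 rose and 7 fell. Of 9 hair follicle progenitor genes, 8 fell and 0 rose (8 and 0 adjusted over the list alone), at a median of -0.95 (5.92 percentile). Runx1, a transcription factor of that list, fell from 24.9 to 2.04 FPKM.

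The highest rises also included Rhov (0.132 to 26.8 FPKM), the long noncoding RNA Malat1 (72.7 to 634), the histone gene H2bu2 (7.28 to 68.3), Omd (1.53 to 19.2), Gadd45b (47.8 to 356), Ctcfl (1.04 to 13.2) and Dusp1 (6.19 to 46.8). The deepest falls also included the amino acid transporter Slc38a2 (185 to 12.2 FPKM), Rnd3 (63.7 to 3.89), Ppp1r10 (23.9 to 0.899), Sertad4 (38.9 to 2.57), Trp53inp1 (12.6 to 0.246), Gemin4 (26.4 to 1.61), Ankrd52 (19.8 to 0.981), Tns3 (19.1 to 0.944) and E2f8 (13.95 to 0.457). Of 10703 genes tested, 1502 rose and 4538 fell at an adjusted p under 0.05, and 457 and 2833 of them by at least 2-fold. With equal FPKM sums 437 rose and 6336 fell, so the balance of directions depended on scaling. With the median of genes of like transcript length subtracted, which evens the directions by construction, 2385 rose and 2527 fell. Change fell with transcript length (Spearman -0.52 across genes, which are not independent replicates), from a median of 0.57 in the shortest of 10 equal bins to -1.14 in the longest.

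**Figure D1:**
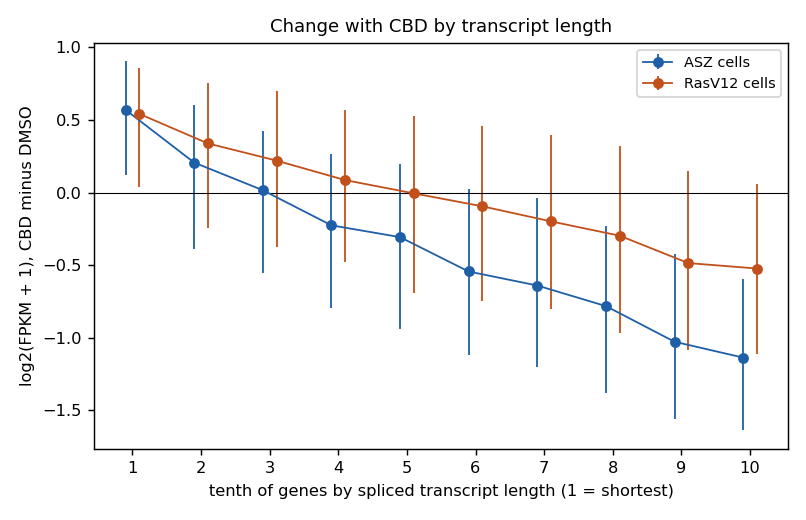
Median log2 change with CBD (log2 FPKM + 1) in each of 10 equal bins of genes by transcript length in nt, for ASZ and RasV12 cells, with bars from the lower to the upper quartile of genes. The medians go from 0.57 to -1.14 in ASZ cells and from 0.54 to -0.52 in RasV12 cells.

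The comparison of CBD with DMSO in RasV12 cells asks the same of cells with activated Ras. Among the Ras/MAPK output genes, where the balance of directions turned with scaling, Hbegf, an EGF receptor ligand, was at 1.49 FPKM in DMSO and 44.5 in CBD (log2 ratio 4.90, SE at most 1.21). Spry1 was at 3.62 and 35.9 FPKM, and Dusp4 at 1.07 and 9.90. Smo was at 39.2 and 40.7 FPKM (adjusted p 0.89), and Gli1 was under 1 FPKM in both groups, at 0.953 and 0.630 (p 0.25 before adjustment). Of 35 G2/M and mitosis genes 15 were lower, with Ccnb1 at 77.9 and 27.2 FPKM, and Nr1d1, a clock gene, was higher, at 33.0 and 746.

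Of 24 Ras/MAPK output genes, 11 rose and 4 fell (11 and 4 adjusted over the list alone), with a median of 0.50 against -0.13 (99.9 percentile), but with equal FPKM sums 5 rose and 7 fell. Phlda1 rose from 8.77 to 37.4 FPKM, and Etv4 from 7.43 to 17.8 without passing under equal FPKM sums. Dusp6 rose from 12.5 to 22.8, without passing with equal fragment mass. Hmga2, a chromatin protein, fell from 10.7 to 2.09 FPKM, Spred2 from 32.9 to 8.42 and Spry2, a feedback inhibitor, from 8.82 to 4.78 (adjusted p 0.048). Of 27 Ras/MAPK pathway components, 3 rose and 11 fell (4 and 11 adjusted over the list alone), at a median of -0.43 (0.86 percentile, and 7.68 with transcript length matched), and 0 rose and 19 fell with equal FPKM sums. Erbb3, an EGF family receptor, fell from 11.7 to 1.22 FPKM. Mapk3, a MAP kinase, rose from 65.9 to 136 FPKM and Hras from 60.2 to 94.4 (adjusted p 0.039), but neither passed with equal FPKM sums. Nras was at 33.7 and 30.4 FPKM (adjusted p 0.67). Of 18 immediate early genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone), at a median of 0.62 against 0.20 (98.1 percentile), and with equal FPKM sums 5 rose and 2 fell, at a median of 0.14. Fos rose from 1.62 to 17.1 FPKM, Fosb from 0.683 to 12.8 and Csrnp1 from 4.17 to 45.1.

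Of 8 Hedgehog target genes, 0 rose and 1 fell (0 and 0 adjusted over the list alone), at a median of 0.18 (82.9 percentile) that was -0.19 with equal fragment mass. Ptch1 was at 0.771 and 1.12 FPKM (adjusted p 0.37), and Osr2, which fell, at 2.62 and 0.869. Of 19 Hedgehog pathway components, 3 rose and 7 fell (4 and 7 adjusted over the list alone), at a median of 0.03 (64.9 percentile) that was -0.35 with equal fragment mass. Gli2 fell from 5.19 to 1.47 FPKM, Sufu from 10.6 to 2.42 and Boc, a co-receptor, from 6.93 to 1.06. Of 66 cilium genes, 17 rose and 17 fell (19 and 17 adjusted over the list alone), at a median of 0.25 against -0.21 (99.99 percentile), but with equal fragment mass 4 rose and 23 fell, at a median of -0.12. Arl3 rose from 57.4 to 133 FPKM and Ift52 from 20.7 to 50.7, without passing under equal FPKM sums, and Tmem67 fell from 2.497 to 0.552 and Arl13b from 6.22 to 2.64. Kif3a was at 9.60 and 7.22 FPKM (adjusted p 0.26) and Ift88 at 2.09 and 3.93 (adjusted p 0.052). With equal fragment mass Kif3a passed as lower (adjusted p 0.017), as it did with equal FPKM sums.

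Of 17 YAP/TEAD and SRF target genes, 7 rose and 3 fell (7 and 3 adjusted over the list alone), at a median of 0.04 (11.03 percentile), and 5 rose and 7 fell with equal fragment mass, at a median of -0.36. Ccn1 rose from 25.4 to 138 FPKM and Amotl2 from 8.08 to 26.6, and Ccn2 fell from 169 to 50.4. Of 30 G1/S and DNA replication genes, 4 rose and 7 fell (4 and 6 adjusted over the list alone), at a median of 0.11 (44.2 percentile), and 1 rose and 10 fell with equal fragment mass, at a median of -0.28. Cdt1, a replication licensing factor, rose from 20.4 to 43.8 FPKM, without passing under equal FPKM sums, and Fen1 fell from 41.7 to 12.2. Of 35 G2/M and mitosis genes, 15 fell and 0 rose (15 and 0 adjusted over the list alone), at a median of -0.41 against 0.33 in random lists, and Mki67 fell from 27.0 to 15.9 FPKM.

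Of 27 stress response genes, 12 rose and 6 fell (13 and 6 adjusted over the list alone), at a median of 0.55 (89.1 percentile), and 2 rose and 7 fell with equal FPKM sums, at a median of -0.01. Ddit3 rose from 19.2 to 184 FPKM, and Slc7a11, a cystine transporter, fell from 11.3 to 2.29. Of 14 heat shock genes, 5 rose and 4 fell (5 and 4 adjusted over the list alone), at a median of -0.22 against 0.59 (0.01 percentile), and 2 rose and 7 fell with equal fragment mass. Hspa8 rose from 669 to 1431 FPKM, without passing under equal FPKM sums, and Dnajb1 fell from 101 to 37.5. All 32 ribosomal protein genes listed rose, at a median of 1.26 against 0.84 (32 adjusted over the list alone). With equal FPKM sums their median was still 0.67 and 9 passed, a count that can reflect standard errors that are upper bounds at the lowest p-value. Of 30 oxidative phosphorylation genes, 21 rose and 0 fell (22 and 0 adjusted over the list alone), at a median of 0.80 (79.6 percentile, and 71.7 with transcript length matched), and 0 rose and 2 fell with equal FPKM sums, at a median of 0.21.

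Of 23 basal keratinocyte genes, 7 rose and 6 fell (7 and 6 adjusted over the list alone), at a median of -0.06 against 0.69 in random lists, and 3 rose and 7 fell with equal fragment mass. The laminin gene Lama3 rose from 36.7 to 111 FPKM, and Dst and Dsg3, which attach cells to matrix and to each other, fell from 160 to 48.7 and from 80.2 to 27.9. Trp63 fell from 92.0 to 53.2 FPKM, and Cdh1, the epithelial cadherin, rose from 56.4 to 95.9, without passing with equal fragment mass. Krt5 was at 3408 and 4583 FPKM (adjusted p 0.36) and Krt14 at 4745 and 3609 (adjusted p 0.36). Of 18 differentiation genes, 8 fell and 0 rose (9 and 0 adjusted over the list alone), at a median of -0.68 (4.05 percentile, and 0.60 with transcript length matched). Krtdap fell from 19.998 to 5.36 FPKM and Ppl, a protein of the cornified envelope, from 39.8 to 12.3. Of 10 hair follicle progenitor genes, 1 rose and 4 fell (1 and 4 adjusted over the list alone), at a median of -0.52 (8.24 percentile). Msx2 rose from 0.672 to 2.56 FPKM, without passing under equal FPKM sums, and Runx1 fell from 33.8 to 7.04.

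The highest rises also included H2bu2 (7.60 to 193 FPKM), Rhov (1.20 to 42.2), the histone gene H4c9 (2.90 to 44.02), Ciart (5.51 to 67.8), Gadd45b (55.7 to 549) and Plk3 (4.89 to 53.5). The deepest falls were those of Ppp1r10 (25.4 to 0.747 FPKM), Ampd3 (20.5 to 0.924), Steap4 (70.4 to 5.41), Gemin4 (34.1 to 2.49), Slc38a2 (179 to 17.5), Trp53inp1 (15.2 to 0.689), Pik3r1 (34.7 to 3.07), Ddx6 (46.5 to 4.98), Ptpn3 (12.01 to 0.646) and Ankrd49 (11.03 to 0.622). Of 11075 genes tested, 2072 rose and 2707 fell, 885 and 1704 of them by at least 2-fold. With equal fragment mass 747 rose and 4002 fell, with equal FPKM sums 253 rose and 4703 fell, and with the median of genes at 10 FPKM subtracted 1105 rose and 3548 fell. Spearman's correlation of change with transcript length was -0.34 across genes, which are not independent replicates.

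**Figure D2:**
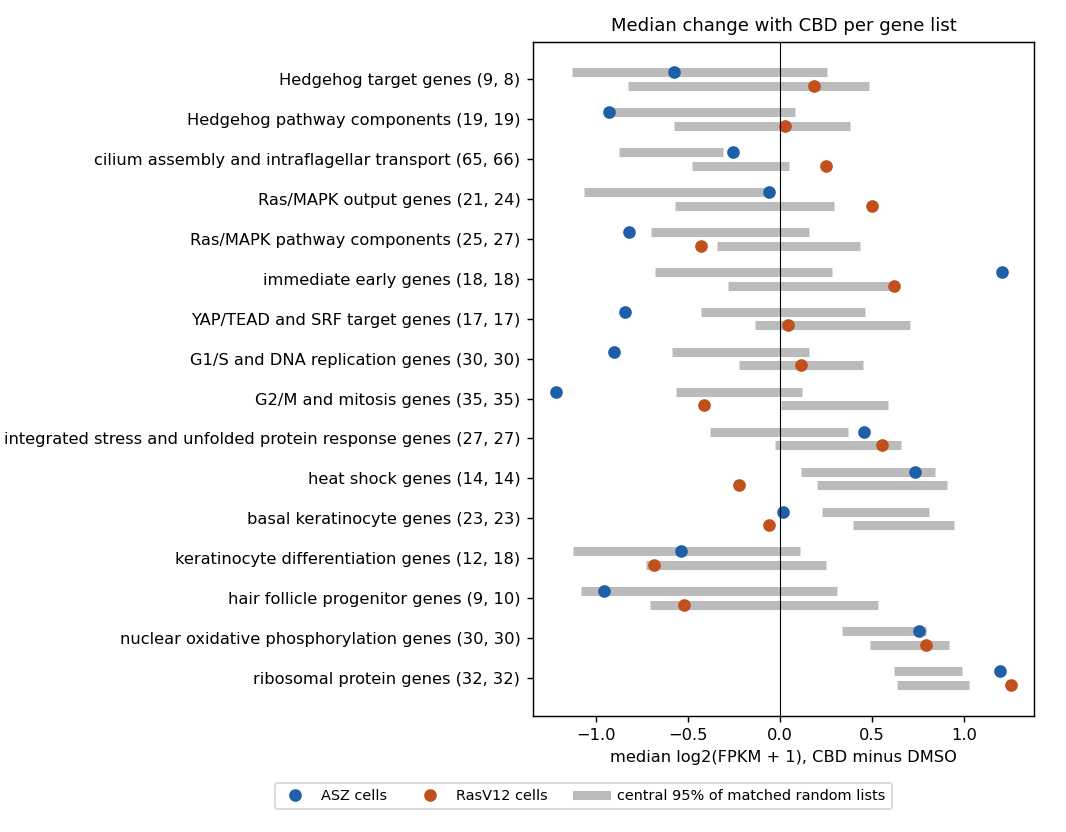
Median log2 change with CBD (log2 FPKM + 1) of the pathway and keratinocyte gene lists in ASZ and RasV12 cells (members tested in parentheses), with the central 95% of medians of random lists of like expression as grey bars. Immediate early genes lie at 1.21 in ASZ cells and G2/M genes at -1.22, both outside their bars.

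**Figure D3:**
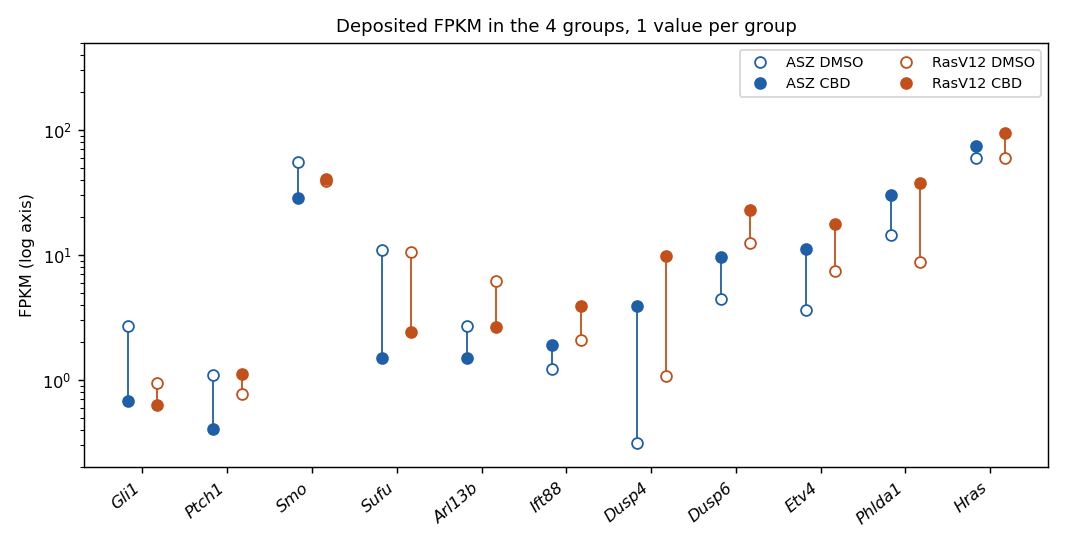
FPKM in DMSO and CBD of Hedgehog, cilium and Ras/MAPK genes, picked from the genes fixed in advance, in ASZ and RasV12 cells, on a log axis, with 1 value per group. Smo goes from 55.7 to 28.8 in ASZ cells and from 39.2 to 40.7 in RasV12 cells. The Ras/MAPK output genes shown, Dusp4, Dusp6, Etv4 and Phlda1, all rose in both lines and do not stand for their list. Ccnd1, Spry2, Spry4, Etv5 and Fosl1, also fixed in advance, are not shown. Of these Ccnd1 passed in neither line and Spry2 fell in RasV12 cells.

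The difference of the log2 ratios, RasV12 minus ASZ, asks where the response to CBD depended on RasV12. Amotl2, an angiomotin family protein, fell in ASZ cells and rose in RasV12 cells (difference 4.53, adjusted p 3.5e-13), as did Jag1, a Notch ligand, at 36.2 and 8.93 FPKM in ASZ cells and 10.2 and 28.5 in RasV12 cells (difference 3.49). Ccn1 differed by 3.30 and Myc by 1.76 (adjusted p 0.0015). In the other direction Egr1 and Dusp1 each differed by -3.89, with Dusp1 at 54.1 and 27.6 FPKM in RasV12 cells, and Hspa1a by -3.65. Each of these genes also passed with equal fragment mass.

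Of the other genes with the highest differences, Gprin3 differed by 4.41 and Kcnj2, a potassium channel, by 4.32. Of those with the lowest, Ctcfl differed by -3.04 and Nanog by -2.99. In ASZ cells Gprin3 was at 4.48 and 0.296 FPKM, Kcnj2 at 2.31 and 0.0831 and Nanog at 0.691 and 5.87. In RasV12 cells none of these passed, nor did Ctcfl (adjusted p 0.34, 0.38, 0.91 and 0.26). Where 1 value is this low, a small change in FPKM gives a large ratio. Smo differed by 1.01 (adjusted p 0.044) and Ptch1 by 1.97 (adjusted p 0.035), but with equal fragment mass the adjusted p were 0.31 and 0.15. Mki67 differed by 1.33 (adjusted p 0.0069, and 0.083 with equal fragment mass), and Krt17 by -1.41 (adjusted p 0.026). The differences of Fos (adjusted p 0.071), Hbegf (0.22) and Dusp6 (0.82) did not pass. Of 30 G1/S genes the change was higher in RasV12 cells for 12 and lower for 0 (5 and 0 with equal fragment mass). It was higher for 6 of 17 YAP/TEAD and SRF target genes (5 with equal fragment mass), for 5 of 19 Hedgehog components (3), for 5 of 65 cilium genes (1), for 5 of 35 G2/M genes (0) and for 3 of 20 Ras/MAPK output genes (3), and lower for 0 in each, except 1 output gene with equal fragment mass. It was lower for 4 of 14 heat shock genes (5) and for 4 of 18 immediate early genes (4), and higher for 0 and 2.

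Of 10405 genes tested, 900 had a higher and 61 a lower ratio in RasV12 cells, and 2255 had an unadjusted p under 0.05. With equal fragment mass the counts were 307 and 89, and with equal FPKM sums 680 and 66, so the balance of directions depended on scaling. Subtracting each line's median gave 178 and 107 and subtracting length medians 85 and 83, but both even the directions by construction. Standard errors at the lowest p-values are upper bounds, which makes this test conservative for such genes. The bound is looser in RasV12 cells, where 1707 genes share the lowest p-value of 5e-05, than in ASZ cells, where 554 are at 0. Changes confined to RasV12 cells therefore pass less readily than changes of like size confined to ASZ cells.

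**Figure D4:**
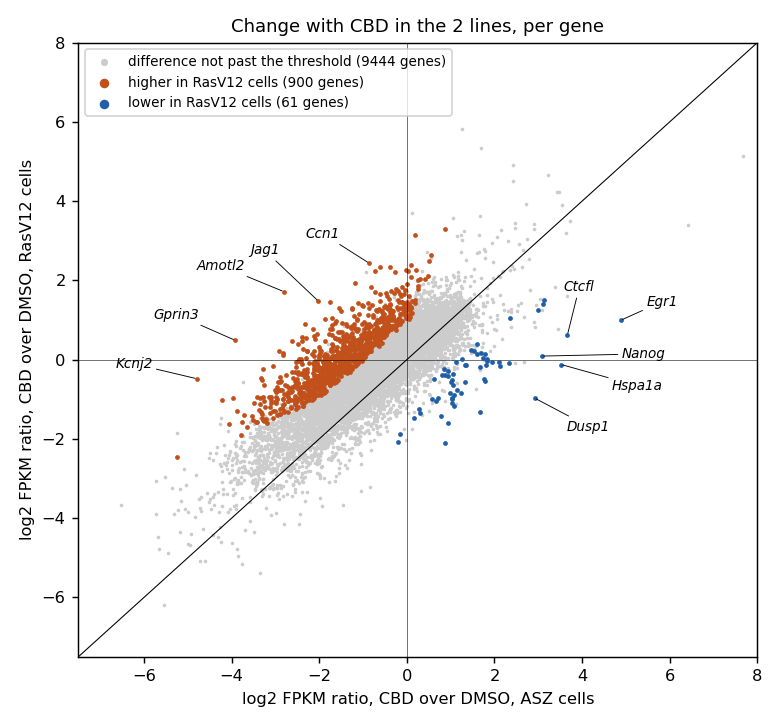
Log2 FPKM ratio of CBD to DMSO in ASZ cells (x axis) and RasV12 cells (y axis), 1 point per gene, with the genes whose ratios differed coloured. Most of the 900 genes with a higher ratio in RasV12 cells lie in a band above the diagonal, and 61 genes lie below it.

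The overlap of the responses asks how much of the change was common to both lines. Of 10437 genes tested in both, 1004 rose in both (280.6 if the calls were independent) and 2425 fell in both (1103), among them Slc38a2, Ppp1r10 and Gemin4. A further 12 rose in ASZ and fell in RasV12 cells, against 360 if independent, and 75 fell in ASZ and rose in RasV12 cells, against 860. The log2 ratios correlated across 10405 genes (Pearson 0.836, Spearman 0.831), which are not independent replicates, and both lines share the length trend.

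Levels in DMSO of the 2 lines are set side by side without a test, because the lines come from separate tables. These tables differed in the kind of p-value and in some gene symbols. Level differences can therefore reflect how each table was made and not only the cells. Vim, an intermediate filament of mesenchymal cells, was at 0.580 FPKM in ASZ and 14.7 in RasV12 cells, Cxcl1, a chemokine, at 1.99 and 116, and Steap4 at 0.152 and 70.4. Dusp6 was at 4.48 and 12.5 FPKM, Dusp1 at 6.19 and 54.1 and Spry2 at 2.15 and 8.82, and Gli1 at 2.73 and 0.953. After centring, the median log2 level difference was outside the central 95% of random lists for 14 lists, marker lists left out. It was above 0 for inflammatory and NF-kB genes (1.40, 100 percentile, 10 of 15 at least 2-fold higher), aryl hydrocarbon receptor targets (0.79, 99.8), interferon response genes (0.78, 100), NRF2 targets (0.59, 100), Wnt targets (0.59, 99.9), immediate early genes (0.49, 99.95), G2/M and mitosis genes (0.47, 100), keratinocyte differentiation genes (0.47, 99.9), hypoxia and glycolysis genes (0.40, 100), Ras/MAPK output genes (0.31, 99.6) and autophagy and lysosome genes (0.22, 99.3). It was below 0 for G1/S genes (-0.47, 0), YAP/TEAD and SRF targets (-0.46, 0.01) and Hedgehog targets (-0.35, 1.14). Of 10925 genes, 436 were at least 2-fold higher in RasV12 cells and 241 lower, and Pearson's correlation across genes, which are not independent replicates, was 0.944.

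Few marker genes of other cell types reached 1 FPKM. Of the fibroblast markers 2 were tested in each line, with 0 changed in ASZ cells (1 fell with equal FPKM sums) and 2 risen in RasV12 cells (0 and 2 adjusted over the list alone), Postn (1.78 to 4.95 FPKM) and Col6a1 (15.8 to 28.9), neither with equal FPKM sums. Of the immune cell markers Cd68 (8.99 to 16.5 FPKM) and Csf1r (0.588 to 1.25) rose in ASZ cells, and Cd68, the 1 tested in RasV12 cells, rose there from 31.7 to 53.8 (2 and 1 adjusted over the list alone), none with equal FPKM sums. Of 2 endothelial markers in ASZ cells, Flt1 rose from 6.92 to 10.5 FPKM, without passing with equal fragment mass, and Pecam1 fell from 15.3 to 9.44 (1 and 1 adjusted over the list alone), while 0 of 2 changed in RasV12 cells. Of 2 melanocyte markers in ASZ cells Tyr rose from 0.276 to 4.11 FPKM and Mitf fell from 7.56 to 1.05 (1 and 1 adjusted over the list alone), and in RasV12 cells Mitf fell from 9.76 to 1.48 and 0 of 2 rose (0 and 1 adjusted over the list alone).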

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

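The tests of scaling here, by fragment mass, by FPKM sum and over all 4 scalings, were chosen only after the differences had been seen; the test of each difference and the centring of each line were chosen before.

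A test of the difference between the lines' changes with CBD set these results apart. Of 10405 genes tested, 900 had a higher ratio in RasV12 cells and 61 a lower one. Named genes were picked in part by this same test and for large changes, so their share passing does not stand for all genes. Of 212 named genes tested 43 passed. The higher ones were Amotl2 (4.53), Gprin3 (4.41), Kcnj2 (4.32), Jag1 (3.49), Ccn1 (3.30), Msx2 (3.12), Bmp2 (3.08), Gas1 (2.99), Dll1 (2.74), Inhba (2.64), Ptgs2 (2.44), Fgf5 (2.39), Cdt1 (2.31), Plk2 (2.22), Tnfaip3 (2.16), Ajuba (2.10), Ptch1 (1.97), Pfkfb3 (1.91), Smad7 (1.77), Myc (1.76), Tnc (1.64), Snai2 (1.53), Notch1 (1.48), Met (1.46), Ift80 (1.42), Znrf3 (1.41), Sox2 (1.37), Mki67 (1.33), Pecam1 (1.20), Smo (1.01) and Klf4 (0.98). The lower ones were Krt17 (-1.41), Hspb1 (-1.51), Malat1 (-1.62), Hspa1b (-1.67), Gsta4 (-1.86), Sbsn (-1.98), Atf3 (-1.99), Nanog (-2.99), Ctcfl (-3.04), Hspa1a (-3.65), Dusp1 (-3.89) and Egr1 (-3.89). With equal fragment mass 17 of the 31 higher and all 12 lower ones also passed. Those that did not were Klf4, Smo, Pecam1, Mki67, Sox2, Znrf3, Ift80, Met, Notch1, Tnc, Smad7, Pfkfb3, Ptch1 and Ptgs2.

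Most differences lay toward RasV12, 93.7% of those past the threshold. Unequal fragment mass alone is argued against as the whole cause, since that share was still 77.5% with equal fragment mass, though the counts fell to 307 higher and 89 lower. With equal FPKM sums the share was 91.2%. These sums shift the 2 lines nearly alike, by 0.52 and 0.59, so that share could hardly move and decides nothing. As higher, 178 genes passed under all 4 scalings, the deposited one included. They were picked by that rule, so their number shows only that their calls do not hang on the choice among these 4. That count was in effect known beforehand from the centred counts, and 61 genes passed as lower under all 4. It says nothing on the share. With each line centred on its median, which evens the directions by construction, the share was 62.5%. Scaling by another factor stays open, because the tables hold no reference of known amount, as do the unequal length trends of the lines, because subtracting length medians evens the directions by construction. The share can also reflect the looser bound on standard errors in RasV12 cells, which was not tested. Changes confined to ASZ cells pass more readily, and most ASZ calls were falls, which count as higher in RasV12. RasV12 itself stays open, untested, as the lines also come from separate tables.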

How the results depend on the processing

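The alternatives by fragment mass, FPKM sum and transcript length were chosen after seeing the data; the others were fixed before. The scalings shift all genes of a line alike by at most 0.59, too little to turn a call, so they test no gene's direction; with length medians 160 genes lower in ASZ cells turned higher. The turns found among the lists are given with them. The cause of the changes was not tested except where the alternative keeps fewer genes by construction (a stricter threshold or a fold minimum). In ASZ cells a 2-fold minimum gave 3290 genes (457 higher, 2833 lower) and the authors' filtered sheets 3953 (502 higher). Of the counts of higher genes, Benjamini-Yekutieli adjustment gave 914 and equal FPKM sums 437 (6336 lower). Length medians, which even the directions by construction, gave 2385 higher and 2527 lower. In RasV12 cells Benjamini-Yekutieli adjustment gave 2865 (1084 higher, 1781 lower), a 2-fold minimum 2589 (885 higher, 1704 lower) and the authors' sheets 2518 (840 higher, 1678 lower). A threshold of 0.01 gave 1317 higher, the median at 10 FPKM 1105 (3548 lower), equal fragment mass 747 (4002 lower) and equal FPKM sums 253 (4703 lower). Differences between lines numbered 467 at 0.01 (431 higher, 36 lower), 285 centred (178 higher, 107 lower), 396 with equal fragment mass (307 higher) and 168 with length medians (85 higher). Genes higher in both lines numbered 624 at 0.01. With a pseudocount of 0.1 the levels in DMSO gave 1057 genes at 2-fold, 700 of them higher in RasV12.

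The other counts stayed within 1.5 times those reported. Centring while keeping each gene's deposited call shifts by at most 0.44, less than any called change, and so shows nothing about stability. Pearson's correlation of the lines ranged from 0.787 to 0.848. Of 219 named genes in ASZ cells, 216 kept their side of the threshold with equal fragment mass and 181 with equal FPKM sums, and of 225 in RasV12 cells 196 and 170. Of 68 list results matched on length too, 60 stayed on their side of the central 95%, 4 left it and 4 entered. Of 70 list results, 68 stayed with a pseudocount of 0.1, 62 with no filter and 60 with a 5 FPKM filter. No paired analysis was possible because the tables hold 1 value per group and no per-library columns. For the same reason leaving out a replicate, another model and other splits of the samples were not run. Depth limits genes near 1 FPKM, where the median implied standard error was 0.47 and 0.51 among genes with a p-value above 0.01.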

Other observations

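All tests of explanations in this part were chosen only after the patterns had been seen, including that of the Zfp genes, whose falls had been noticed before the test.

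Of the 15 further lists given here, the median lay outside the central 95% of random lists of like expression only for Notch target genes and histone genes in ASZ cells and for EGF and FGF family ligands in RasV12 cells. No transcript length was known for the histone genes, so their place could not be checked against the length trend. Medians and percentiles are as deposited, and with equal FPKM sums each median above 0 among them fell below 0. Of 18 TGF-beta and BMP response genes, 1 rose and 10 fell in ASZ cells and 6 rose and 2 fell in RasV12 cells (the same numbers adjusted over the list alone), and in RasV12 cells 5 rose and 5 fell with equal fragment mass and 4 and 6 with equal FPKM sums, at medians of -0.69 (8.78 percentile) and 0.32 (78.8). Inhba, an activin subunit, fell from 35.8 to 20.4 FPKM in ASZ cells and rose from 6.92 to 24.5 in RasV12 cells, and the change was higher in RasV12 cells for 7 of 17 members and lower for 0 (4 and 0 with equal fragment mass). Of 8 Notch target genes 1 rose and 5 fell in ASZ cells, at a median of -1.57 (0.18 percentile), and of 9 in RasV12 cells 3 rose and 3 fell (1 and 4 with equal fragment mass), at -0.16 (35.7). Of 8 Wnt target genes 6 fell and 0 rose in ASZ cells, and of 11 in RasV12 cells 3 fell and 0 rose (2 and 0 adjusted over the list alone), at medians of -0.87 (17.0 percentile) and -0.26 (46.8). Of 17 EMT and mesenchymal genes 4 rose and 4 fell in ASZ cells (2 and 7 with equal FPKM sums) and 7 rose and 2 fell in RasV12 cells (7 and 3 adjusted over the list alone, and 5 and 6 with equal FPKM sums), at medians of 0.35 (96.0 percentile, and 99.4 with transcript length matched) and 0.25 (48.1). Fn1, fibronectin, rose from 151 to 356 and from 60.8 to 400 FPKM. Of 10 EGF and FGF family ligands 1 rose and 4 fell in ASZ cells, and of 11 in RasV12 cells 4 rose and 0 fell (4 and 3 with equal fragment mass, and 2 and 3 with equal FPKM sums), at medians of -0.19 (90.04 percentile) and 0.40 (97.6, and 97.4 with transcript length matched). Of 8 inflammatory and NF-kB genes 1 rose and 0 fell in ASZ cells (0 and 2 with equal FPKM sums), and of 15 in RasV12 cells 4 rose and 2 fell (5 and 2 adjusted over the list alone, and 2 and 3 with equal fragment mass), at medians of 0.16 (97.0 percentile) and 0.40 (97.2). Ptgs2 rose from 16.6 to 30.3 FPKM in ASZ cells, without passing under equal FPKM sums, and from 3.85 to 38.2 in RasV12 cells. Of 10 interferon response genes 1 rose and 4 fell in ASZ cells, and of 19 in RasV12 cells 3 rose and 3 fell (2 and 4 with equal fragment mass), at medians of -0.06 (94.0 percentile) and 0.14 (95.9).

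Of 20 p53 target genes 4 rose and 10 fell in ASZ cells, and of 21 in RasV12 cells 5 rose and 6 fell (6 and 7 adjusted over the list alone, and 3 and 10 with equal fragment mass), at medians of -0.52 (23.7 percentile) and -0.21 (13.6). Of 19 NRF2 target genes 6 rose and 6 fell in ASZ cells (3 and 8 with equal FPKM sums) and 5 rose and 4 fell in RasV12 cells (2 and 6 with equal fragment mass), at medians of 0.01 (70.8 percentile) and -0.04 (6.37), with Gclc, of glutathione synthesis, falling from 64.7 to 10.1 FPKM in the latter. Of 4 aryl hydrocarbon receptor targets 2 fell in ASZ cells and 1 in RasV12 cells, and 0 rose, at medians of -0.10 (82.2 percentile) and 0.10 (38.2); Cyp1b1 fell from 52.5 to 5.19 and from 69.1 to 9.76 FPKM. Of 21 cholesterol biosynthesis genes 2 rose and 7 fell in ASZ cells, and 0 rose and 3 fell in RasV12 cells, at medians of -0.06 (27.0 percentile) and 0.09 (8.01). Of 22 hypoxia and glycolysis genes 10 rose and 3 fell in ASZ cells (10 and 4 adjusted over the list alone, and 5 and 5 with equal FPKM sums), and of 23 in RasV12 cells 9 rose and 4 fell (10 and 4 adjusted over the list alone, and 2 and 6 with equal FPKM sums), at medians of 0.35 (67.9 percentile) and 0.44 (39.6). Of 30 dynein, dynactin and tubulin genes 6 rose and 7 fell in ASZ cells and 11 rose and 8 fell in RasV12 cells, where 3 rose and 10 fell with equal fragment mass, at medians of 0.05 (8.73 percentile) and 0.23 (4.16, and 2.39 with transcript length matched). Dync1h1, the heavy chain of cytoplasmic dynein, was at 19.0 and 23.8 FPKM in ASZ cells (adjusted p 0.20) and rose from 13.5 to 38.7 in RasV12 cells. Of 27 autophagy and lysosome genes 9 rose and 3 fell in ASZ cells (9 and 2 adjusted over the list alone), and 12 rose and 2 fell in RasV12 cells, but 1 rose and 6 fell, and 1 rose and 3 fell, with equal FPKM sums, at medians of 0.26 (68.6 percentile) and 0.39 (26). Of 12 histone genes in ASZ cells and 14 in RasV12 cells 4 rose and 1 fell in each (4 and 4, and 3 and 3, with equal FPKM sums), at medians of 0.21 (98.8 percentile) and -0.34 (34.6), with H2bc4 rising from 10.4 to 55.1 and from 7.79 to 39.8 FPKM. Where no count over the list alone is given, it was the same.

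The fall of log2 change with transcript length is argued not to come from the correction of short transcripts alone, since Spearman's correlation was still -0.369 in ASZ and -0.239 in RasV12 cells at 2000 nt or more. Slower transcription of long genes is argued against by coefficients of genomic span of 0.0126 and 0.0227 per SD beside spliced length. Lower RNA integrity in the CBD libraries may account for it, as coding length (-0.245 and -0.116 log2 per kb) and 3' UTR length (-0.149 and -0.0759) both carried negative coefficients. Lower RNA synthesis with loss of short-lived mRNAs stays open too, since the Zfp genes lay at the 0 percentile of lists matched on expression and length in both lines (median -1.08 against -0.75, and -0.85 against -0.43), but these data hold no half-lives. Both could act together, and no integrity values or per-library values are at hand.

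The rise of immediate early genes is argued not to come from the length trend, with percentiles of 100 and 98.0 among lists matched on expression and length, nor in ASZ cells from scaling, as 11 rose and 2 fell with equal FPKM sums. In RasV12 cells scaling cannot be told apart from a rise, as their median of 0.62 was 0.28 with equal fragment mass and 0.14 with equal FPKM sums, where 5 rose and 2 fell, too few calls to decide. For the place of the Ras/MAPK output genes above matched lists, the length trend is likewise argued against (98.3 and 99.9 percentiles). In ASZ cells these genes did not rise as a list, with 6 higher and 7 lower at a median of -0.06. They only fell less than matched lists there. Scaling may account for more of them being called higher than lower in RasV12 cells, as 5 rose and 7 fell there with equal FPKM sums, but it moves all genes alike and so not their place among other genes. An effect of CBD on signalling to immediate early genes is a candidate explanation in ASZ cells, but it was not tested. The rise itself was found and checked on the same data. Effects of handling the cultures stay open, untested.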
